A study of Rattus norvegicus with 24 samples.

How the data were processed

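Total RNA of PC12 cells at passages 18 to 20 was sequenced in 24 libraries, per the labels 2 stable lines at 4 times with 3 replicates each. Per the labels' protocols, libraries were made with a stranded total RNA kit with depletion of ribosomal RNA and sequenced as pairs of 100 bases in 3 lanes on an Illumina HiSeq2500. The authors deposited 1 table of read counts per library, whole numbers per gene symbol with no normalization and 5 summary lines at the end. Per the submitters' processing notes the tools were FastQC 0.11.2, TopHat2 2.0.10, Picard 1.117, HTSeq 0.5.4p5 and edgeR (no version given), and the genome build was rn5. The roles of these tools, the gene annotation, the strand setting of the counting and the treatment of duplicates are not given in the sources used here. If strand was not used, reads of overlapping antisense genes cannot be told apart, and genes with near-identical copies may share or lose reads.

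Each table listed 17055 genes, of which 13187 had a count in some library. The summary lines were left out of library sizes and tests. Reads outside annotated genes made up 47.8% to 52.9% of reads that were assigned, ambiguous or outside genes, ambiguous reads 0.159% to 0.242%, and alignments set aside as not unique numbered 73.7 to 103 per 100 such reads. Depth on genes was 8679560 to 14486248 counts per library, so a floor of 3 counts per library stood at 0.207 to 0.346 CPM. For a named gene with no more than that floor, on average, in a group, the ratio of summed counts scaled for depth is given with its exact 95% counting interval, or a bound against the floor where all counts were 0. Such floors and counting intervals cover counting error only. The 10 most counted genes took 5.33% to 7.19% of counts. No coordinates are given, since the reference table used here is of assembly GRCr8 and not rn5. It served to check names, and 16568 symbols (97.1%) matched it with synonyms, 14175 of them directly.

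Groups were taken from the labels and never from file names, which disagree with the labels for 18 of the 24 libraries. In every comparison the groups were those of the labels. In the Results, file names bear only on the doubt over the labels and the reading of the line and time differences. In the closing section they entered the test of mislabelling. They also entered the reading of the contrast of 3 d and 10 d against 6 h and 24 h. That contrast has the labels' groups and is also the contrast of the lines by the file names. The protocol calls the 3 libraries of a group biological replicates, and nothing in the labels says that they came from separate cultures, so p-values measure the spread between these samples. Counts of replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 1.98 to 11.3 and numbers 1 and 3 the closest pair in all 8 groups, so no pair was treated as 1 library deposited in duplicate. Separately prepared libraries of the same RNA would also exceed that noise, so this does not show separate cultures.

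The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, on counts with TMM factors (0.981 to 1.02), 1 coefficient per group and all 24 libraries in 1 fit with 16 residual degrees of freedom. Genes were kept with edgeR's filter by group (minimum count 10, minimum total 15), which left 9994. Benjamini-Hochberg adjustment was applied over these genes, with a threshold of 0.05. The common biological coefficient of variation was 5.75%. The comparisons were α1ACT against vector at each time and on average, the joint effect of time and 10 d against 6 h in each line, and the interaction of line and time. CPM values are relative to counts on genes after TMM scaling, and distances and principal components use log2 CPM with a prior count of 2. Fold changes come from the edgeR fit unless counts are given.

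The 25 gene lists covered catecholamine and chromaffin cells, neurite and neuronal differentiation, synaptic vesicles, calcium channels and handling, Purkinje and cerebellar cells, axon guidance, immediate early genes, mitosis, replication, histones, cholesterol synthesis, endoplasmic reticulum stress with the amino acid response, heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, p53 targets, interferon and antigen presentation, extracellular matrix, genes tied to α1ACT in earlier work, nuclear-retained RNAs, and epithelial, fibroblast, immune and Schwann or glial cells. Lists with at least 5 tested members, 21 of them, were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over lists within a comparison, with an estimated correlation and fry beside it. No list call held with an estimated correlation in the planned comparisons.

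Named genes were the 6 with the largest rise and the 6 with the largest fall per comparison, among genes past the threshold with a mean of at least 2 CPM and no overlap between the libraries of the 2 groups (for the average, the same sign at all 4 times). For the interaction they were the 6 with the smallest p. Up to 4 members with the smallest p were named from each list described, and Cacna1a, Grn, Atp2b2 and Btg1 always. Some genes that this rule would name are not reported here. Genes known only by an identifier were passed over, at most 2 for any direction of a comparison. The groups, tests, lists, naming rule and alternatives other than those named as added later were fixed before the data were examined.

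Alternatives were DESeq2 1.42.0 (Wald and likelihood ratio tests), RLE factors, no filter on low counts, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were leaving out all libraries of 1 replicate number, library sizes without scaling factors, and the contrast of 3 d and 10 d against 6 h and 24 h.

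Replicate numbers come from the sample titles, and the labels do not say what they share. Deviations from the group means of same-numbered libraries correlated across genes at 0.124, 0.318 and 0.139 for the lines at 3 d, each above 0.1, so the numbers were taken to pair these samples. With the replicate block 4147 genes differed at 3 d. No other comparison met this rule, although the lines at 6 h came close, at 0.164, 0.342 and 0.0980.

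The scripts were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed, 50 at each of 1.25, 1.5, 2 and 4-fold. For the line difference at 6 h, edgeR recovered 60%, 92%, 98% and 98% of them among 9902 genes and called 5 unchanged genes. For the average line difference it recovered 86%, 96%, 100% and 100% among 9896 genes, with 8 unchanged genes called. For 10 d against 6 h in the vector line it recovered 66%, 94%, 94% and 98% among 9911 genes, with 6 unchanged genes called, and for the interaction 24%, 88%, 90% and 98% among 9907 genes, with 15 called. DESeq2 recovered 56%, 94%, 96% and 98% for the line difference at 6 h among 9994 genes, with 8 called. A simulated list raised 1.5-fold had a camera adjusted p of 7.40e-79 at 6 h, and 0 of 20 unchanged lists of 25 genes were called. Each gene was drawn independently, so simulated lists had no correlation between members. The list result therefore does not check list calls in the real data. With only 200 genes changed, the simulation also does not check scaling or error rates where far more genes differ.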

Results

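RNA was measured in 24 libraries of PC12 cells, a rat line from a pheochromocytoma of the adrenal medulla that is widely used as a model of neural crest and neuronal cells. One stable line carried the empty pcDNA3 vector and the other expressed human α1ACT, the carboxy-terminal fragment encoded by the calcium channel gene CACNA1A, which acts in the nucleus as a transcription factor. Each line was labelled as sampled at 6 h, 24 h, 3 d and 10 d, with 3 replicates in each of the 8 groups. The labels do not state the event from which the times were counted, and with 1 stable line of each kind a difference between lines is not separated from other differences between these 2 lines. Counts assigned to genes ranged from 8679560 to 14486248 per library, with a median of 11663500. The α1ACT 10 d group was the shallowest, at 9424400 ± 688926 counts (SD, n = 3), and the vector 24 h group the deepest, at 12911533 ± 1837034. The question addressed was which genes α1ACT alters over time, for a factor studied for its part in neonatal survival and in the development of the cerebellum.

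The line and time of each library are those of the labels throughout, and they carry a doubt that bears on every direction given here. The deposited files are named in the form of the sample titles, and for 18 of the 24 libraries the name gave another time point than the label, with another line as well in 12 of these. Replicate numbers matched in all 24. By expression, the 8 labelled groups formed 4 close pairs. The 6 h and 3 d groups of the vector line lay 0.194 apart (root mean square difference of log2 CPM over tested genes) and those of the α1ACT line 0.185. The 24 h and 10 d groups of the vector line lay 0.222 apart and those of the α1ACT line 0.215, and the next nearest pair of groups 0.369 apart. By the file names the groups of each close pair share a time. If the file names are right, each line difference at a labelled time compares different times within the same line. Each comparison of 10 d with 6 h within a labelled line would then compare different lines at different times. "Vector" and "α1ACT" stand here for the lines as labelled, "higher" and "lower" for α1ACT relative to vector unless times are compared, and log2 fold changes are given ± SE.

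**Figure D1:**
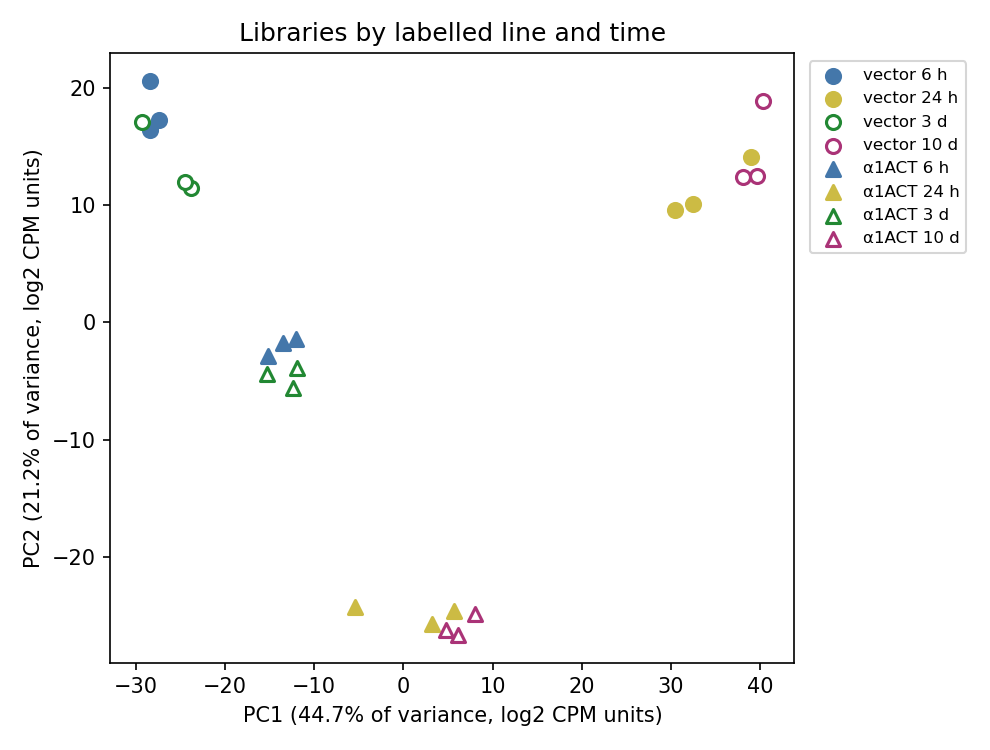
Scores of the 24 libraries on principal components 1 (44.7% of variance) and 2 (21.2%), in log2 CPM units, 1 point per library; circles mark the vector line, triangles the α1ACT line, colours the labelled time, filled symbols 6 h and 24 h, and open symbols 3 d and 10 d. Within each labelled line the 6 h libraries lie with the 3 d libraries and the 24 h libraries with the 10 d libraries.

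**Figure D2:**
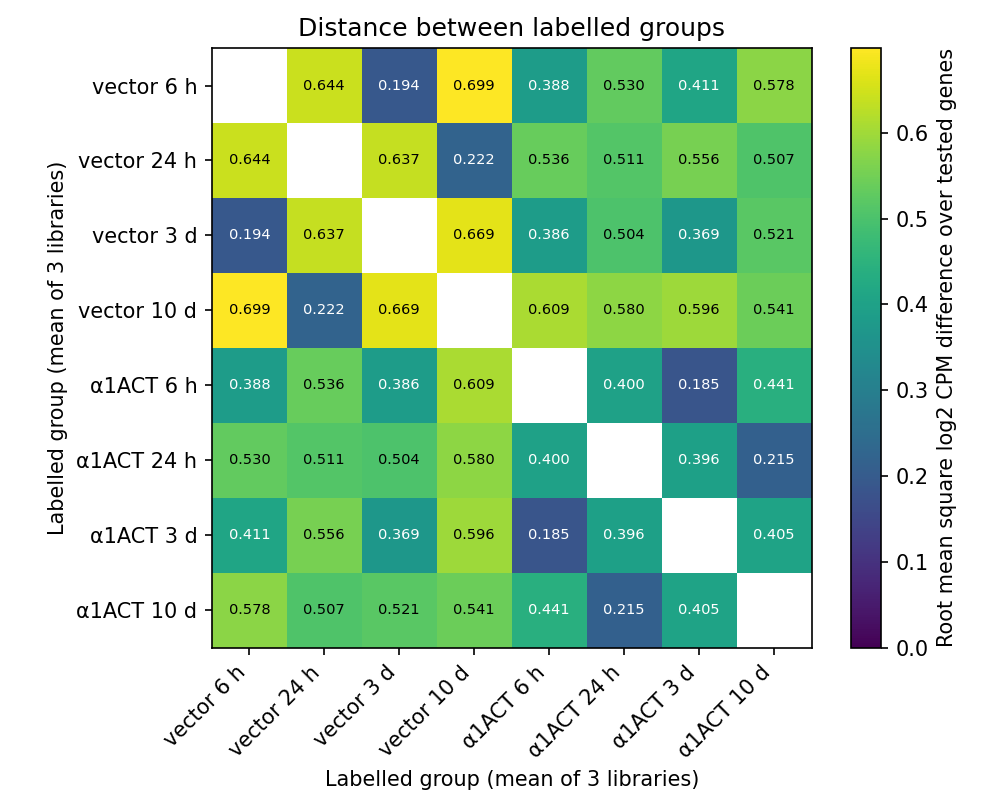
Root mean square difference of log2 CPM over the 9994 tested genes between the means of the 8 labelled groups (3 libraries each). The darkest cells off the diagonal are those of 4 pairs of groups, each shown on both sides. These pairs are 6 h with 3 d and 24 h with 10 d within each labelled line, at 0.185 to 0.222.

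Cacna1a, the rat gene of the channel from which α1ACT derives, was detected in every library. It stood at 14.8 ± 0.579, 16.9 ± 1.58, 13.2 ± 0.338 and 17.2 ± 3.26 CPM in the vector line at 6 h, 24 h, 3 d and 10 d, and at 16.4 ± 1.57, 11.7 ± 1.38, 17.2 ± 1.69 and 13.4 ± 0.240 CPM in the α1ACT line (SD, n = 3 per group). The human transgene has no feature of its own in the counts, so Cacna1a does not check which libraries carry it. Whether reads of the transgene were counted under Cacna1a was not examined, so its values may not be of the rat gene alone. Among genes tied to α1ACT in earlier work, Atp2b2, a plasma membrane calcium pump, was 1.84-fold higher at 6 h (0.88 ± 0.09) and 1.67-fold higher at 3 d (0.74 ± 0.09). At 24 h its difference of -0.20 ± 0.09 did not pass (edgeR adjusted p = 0.0631), and at 10 d it was lower, by -0.23 ± 0.09 (adjusted p = 0.0331). That call ended without α1ACT replicate 2 (0.188), α1ACT replicate 3 (0.0568) or vector replicate 2 of that time (0.123), and in a fit of these 6 libraries alone (0.0510). Grn, the progranulin gene, was 1.45-fold lower at 24 h and 1.42-fold lower at 10 d, and Btg1, an antiproliferative regulator, 1.56-fold and 1.81-fold lower at those times. Neither passed at 6 h (Grn 0.11 ± 0.05, Btg1 0.23 ± 0.11) or 3 d (Grn 0.08 ± 0.05, Btg1 0.14 ± 0.11), although Btg1 did at 6 h with no filter on low counts (adjusted p = 0.0480). With library sizes in place of scaling factors both were higher at 6 h, Grn by 0.15 (adjusted p = 0.0202) and Btg1 by 0.28 (adjusted p = 0.0466) on the log2 scale. Of these 4 genes, 1 rose and none fell at 6 h (3 rose with library sizes), 2 rose at 3 d, 3 fell at 24 h and 4 fell at 10 d. Adjusted over the list alone, 1 rose at 6 h, 2 rose at 3 d, and 4 fell at 24 h and at 10 d. The call of Cacna1a ended at 3 d without α1ACT replicate 3 (adjusted p = 0.0713) and at 10 d without vector replicate 2 (0.140).

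**Figure D3:**
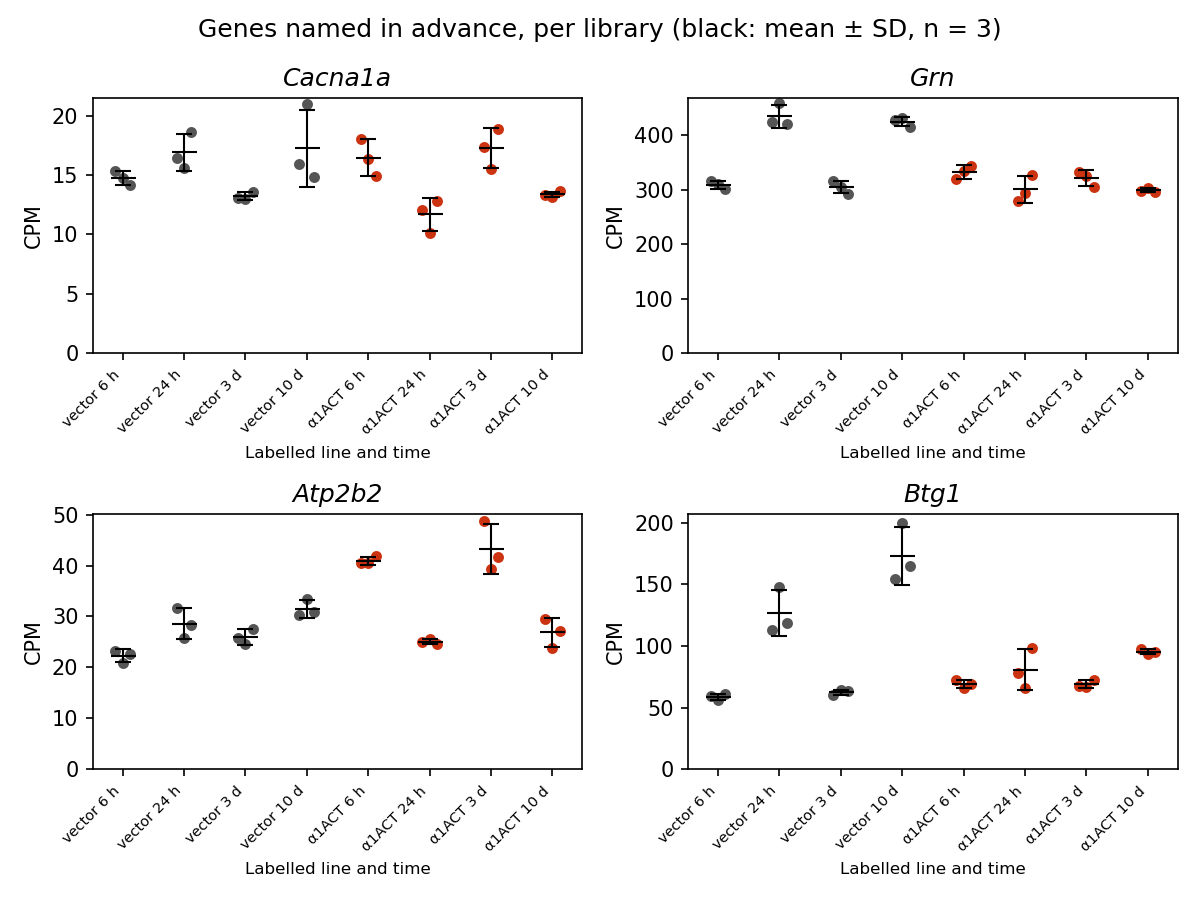
CPM in each library of Cacna1a, Grn, Atp2b2 and Btg1 (points), with the mean and SD of each labelled group (black, n = 3); grey points are the vector line and red points the α1ACT line. Atp2b2 stood at 22.2 ± 1.28 CPM in the vector line and 40.9 ± 0.804 CPM in the α1ACT line at 6 h.

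At the labelled 6 h, 16 of 26 immediate early genes, 20 of 27 mitosis genes and 12 of 24 neurite genes were lower in the α1ACT line, and 12 of 23 interferon and antigen presentation genes were higher. The 4 lists passed camera with its preset correlation, but none did with an estimated one (adjusted p = 0.0839 to 0.805 with an estimated correlation). Kcnh1, a voltage-gated potassium channel, was 10.1-fold higher (3.33 ± 0.27), at 13.3 ± 0.940 against 1.34 ± 0.559 CPM (SD, n = 3). Smtnl2 (4.81-fold), the Hippo pathway transcription factor Tead2 (3.73-fold), the lipase inhibitor G0s2 (3.72-fold), Plekhb1 (3.74-fold) and the matrix proteoglycan Dcn (3.47-fold) also rose. The adhesion gene Mpzl2 was 21.2-fold lower (-4.40 ± 0.35), at 0.333 ± 0.0819 against 7.29 ± 0.702 CPM. Ugt1a2, a glucuronosyltransferase of a locus whose transcripts share exons, was lower. It had 7 against 131 counts, a 19.9-fold difference (95% counting interval 9.41 to 50.6). Fosl1, a subunit of the AP-1 transcription factor, was 13.6-fold lower, and the adhesion molecule Icam1 (5.04-fold), the focal adhesion gene Tgfb1i1 (4.96-fold) and the myosin light chain Myl9 (4.80-fold) fell with it.

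Of 26 tested immediate early genes 16 fell, 2 rose and 8 did not pass, with 19 falling when adjusted over the list alone (camera adjusted p = 6.60e-05, adjusted p = 0.405 with an estimated correlation). Klf6 was 2.34-fold lower, Arc 2.51-fold and Klf4 3.47-fold. Among 27 mitosis genes 20 fell and none rose, with 22 falling over the list alone (camera adjusted p = 3.75e-06, adjusted p = 0.805 with an estimated correlation), and Prc1 (-0.66 ± 0.08), Ccna2 (-0.58 ± 0.09), Aurkb (-0.51 ± 0.10) and Cenpf (-0.46 ± 0.07) led by p. The neurite and neuronal differentiation list had 12 lower and 3 higher of 24 (13 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.00513, adjusted p = 0.112 with an estimated correlation). Its leading members were Sprr1a, induced in regenerating neurons (-1.47 ± 0.15), the microtubule-binding kinase Dclk1 (-1.40 ± 0.15), the secreted neuropeptide precursor Vgf (-1.45 ± 0.18) and the neurofilament Nefm (-0.80 ± 0.10). Interferon and antigen presentation genes rose in 12 of 23 and fell in 1, the same counts over the list alone (camera adjusted p = 0.000687, adjusted p = 0.0839 with an estimated correlation), with Mx2 3.05-fold, Ifi44 1.82-fold and Stat2 1.79-fold higher. The epithelial keratins Krt8 (-0.77 ± 0.10) and Krt18 (-0.70 ± 0.17) were lower at this time as well. Reads outside annotated genes were 49.6% ± 0.587 of the reads assigned, ambiguous or outside genes in the α1ACT libraries and 48.7% ± 0.842 in the vector libraries (SD, n = 3).

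In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 4162 of 9994 genes differed between the lines at 6 h, 2045 higher and 2117 lower, and 289 of them by at least 2-fold. The share of higher genes among those called was 49.1%, and 60.3% with library sizes in place of scaling factors. Without all libraries numbered 1 or all numbered 3 the count was 2580 or 2637.

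At the labelled 24 h, most tested genes of cell division, replication, sterol synthesis and histones were higher in the α1ACT line, and 23 of 31 genes of the endoplasmic reticulum stress and amino acid response were lower. These lists passed camera with its preset correlation, but not with an estimated one (adjusted p = 0.230 to 0.398 with an estimated correlation). All 27 tested mitosis genes rose, 27 of them adjusted over the list alone (camera adjusted p = 9.68e-20, adjusted p = 0.230 with an estimated correlation), among them Top2a (3.01-fold), Prc1 (2.69-fold), the spindle kinesin Kif11 (2.46-fold) and the checkpoint kinase Bub1 (2.35-fold). All 32 replication genes rose, 32 over the list alone (camera adjusted p = 1.41e-19, adjusted p = 0.230 with an estimated correlation), led by Tk1 (1.97 ± 0.11), Gins1 (1.74 ± 0.11), Rrm1 (1.29 ± 0.08) and Pola1 (1.03 ± 0.07). Histone genes rose in 13 and fell in 1 of 14, with the same counts over the list alone (camera adjusted p = 2.90e-06, adjusted p = 0.398 with an estimated correlation). Hist1h1a, a linker histone, was 5.50-fold higher, at 153 ± 45.4 against 27.6 ± 2.97 CPM (SD, n = 3). Reads shared among near-identical histone genes make single members uncertain.

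Cholesterol synthesis genes rose in 21 and fell in 1 of 23 (22 and 1 over the list alone, camera adjusted p = 1.25e-07, adjusted p = 0.282 with an estimated correlation). Fdps, which makes farnesyl pyrophosphate, was 2.69-fold higher. Scd1, the desaturase that makes oleate, was 5.55-fold higher (2.47 ± 0.20), though its α1ACT libraries spread widely at 559 ± 234 CPM. Oxidative phosphorylation genes rose in 21 and fell in 2 of 37, the same over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.406 with an estimated correlation), with a median of 0.26 and 0.57 ± 0.04 for Atp5b. Hypoxia and glycolysis genes rose in 17 and fell in 7 of 32, likewise over the list alone (camera adjusted p = 0.00201, adjusted p = 0.406 with an estimated correlation), with Pgk1 1.79-fold and Pdk1 1.83-fold higher.

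Genes of the endoplasmic reticulum stress and amino acid response fell in 23 and rose in 1 of 31, the same counts over the list alone (camera adjusted p = 1.25e-07, adjusted p = 0.312 with an estimated correlation). Sel1l, part of the degradation machinery of misfolded proteins, was 3.77-fold lower, Herpud1 2.38-fold, the chaperone Hspa5 2.32-fold and Sesn2 1.86-fold. Of 16 p53 targets 8 fell and 1 rose, also over the list alone (camera adjusted p = 0.00818, adjusted p = 0.406 with an estimated correlation), including Gadd45a (2.39-fold lower) and Bbc3 (1.95-fold lower). Immediate early genes fell in 12 and rose in 1 of 26, the same over the list alone (camera adjusted p = 0.00953, adjusted p = 0.406 with an estimated correlation), with Myc 3.39-fold and Atf3 3.33-fold lower. Axon guidance genes fell in 8 and rose in 2 of 19, again the same over the list alone (camera adjusted p = 0.0478, adjusted p = 0.406 with an estimated correlation). The netrin receptor Unc5b was 4.81-fold lower, while the guidance ligand Slit2 was 2.84-fold higher. Extracellular matrix genes fell in 5 and rose in 1 of 11, unchanged in number over the list alone (camera adjusted p = 0.0478, adjusted p = 0.230 with an estimated correlation).

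The basement membrane collagen Col4a1 was 14.0-fold lower at 24 h (-3.81 ± 0.35), at 0.532 ± 0.342 against 7.94 ± 1.33 CPM. The teneurin Odz4 was 16.5-fold lower, followed by the fatty acid hydroxylase Fa2h (12.5-fold), the olfactory receptor Olr1386 (10.1-fold, of a family with near-identical copies), the cytochrome P450 Cyp4b1 (9.70-fold) and the artemin receptor Gfra3 (8.83-fold). Beside Scd1 and Hist1h1a, the largest rises by the fixed rule were those of Rgs2, a regulator of G protein signalling (8.19-fold), the serotonin receptor Htr3a (4.83-fold), the matrix gene Tgfbi (4.57-fold) and Hsd11b1, which regenerates active glucocorticoid (4.54-fold). The keratins Krt8 (0.78 ± 0.10) and Krt18 (1.15 ± 0.19) were higher at this time, with the division genes. They were the only higher ones of 6 tested epithelial genes, of which Cldn4 (-0.57 ± 0.07) and Epcam (-0.43 ± 0.09) were lower, the same counts over the list alone. That list did not pass as a set (camera adjusted p = 0.983), and its median of -0.26 and mean of 0.07 differed in sign. The share of reads outside annotated genes was 51.6% ± 0.589 in the α1ACT and 50.4% ± 0.362 in the vector libraries (SD, n = 3). In all 5542 of 9994 genes differed by edgeR's quasi-likelihood test, 2662 higher and 2880 lower, and 618 by at least 2-fold.

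At the labelled 3 d, 18 of 26 immediate early genes were lower and 12 of 23 interferon and antigen presentation genes higher in the α1ACT line. Neither list passed camera with an estimated correlation (adjusted p = 0.275 and 0.184 with an estimated correlation). Fosl1 was 21.8-fold lower (-4.45 ± 0.31), at 0.736 ± 0.232 against 16.1 ± 4.46 CPM (SD, n = 3), and Mpzl2 17.1-fold lower. Fam26e (4.55-fold), Tgfb1i1 (4.13-fold), Mlf1 (4.12-fold) and the sphingomyelin synthase Sgms2 (4.05-fold) also fell. Kcnh1 was 6.80-fold higher, Smtnl2 4.93-fold, Bcar3 4.62-fold, G0s2 4.01-fold, the serotonin receptor Htr6 3.93-fold and the monocarboxylate transporter Slc16a5 3.41-fold. Immediate early genes fell in 18 and rose in 1 of 26 (19 and 1 over the list alone, camera adjusted p = 2.12e-06, adjusted p = 0.275 with an estimated correlation). Interferon and antigen presentation genes rose in 12 and fell in 2 of 23 (14 and 2 over the list alone, camera adjusted p = 0.00633, adjusted p = 0.184 with an estimated correlation), with Ifi44 1.64-fold and Stat2 1.45-fold higher. Mitosis genes were mixed, with 7 higher and 4 lower of 27 (the same over the list alone, camera adjusted p = 0.915), a median of -0.02 and a mean above 0. With library sizes 7 were higher and 2 lower, and the median was above 0. Epithelial genes were lower in 4 and higher in 1 of 6, as over the list alone (camera adjusted p = 0.326), with none higher under RLE factors. Reads outside annotated genes made up 49.9% ± 0.286 in the α1ACT and 48.8% ± 0.571 in the vector libraries. Thbs1, a matrix glycoprotein, had 31 counts over the vector libraries and 1 over the α1ACT libraries, a ratio of 33.1 scaled for depth (95% counting interval 5.52 to 1350). By edgeR's quasi-likelihood test 3934 of 9994 genes differed, 1991 higher and 1943 lower, and 253 by at least 2-fold. The share of higher genes was 50.6%, and 59.7% with library sizes. Without all libraries numbered 1 or all numbered 3 the count was 2462 or 2449. The tests at 3 d given here leave out the replicate number as a block, and with it 4147 genes differed.

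At the labelled 10 d, 25 of 27 mitosis, 30 of 32 replication and 22 of 23 sterol synthesis genes were higher in the α1ACT line, and 25 of 31 stress response genes lower. These lists passed camera with its preset correlation, but not with an estimated one (adjusted p = 0.242 for each with an estimated correlation). Rgs2 was 19.4-fold higher (4.28 ± 0.39), at 13.1 ± 6.04 against 0.652 ± 0.211 CPM (SD, n = 3), and Scd1 8.49-fold, at 801 ± 185 against 94.2 ± 5.29 CPM. The monoacylglycerol lipase Mgll (6.40-fold), the MAX-binding repressor Mxd3 (6.10-fold), the coactivator Cited1 (5.84-fold) and Hist1h1a (5.30-fold) also rose. Odz4 was 22.7-fold lower (-4.50 ± 0.19), the RNA-binding protein gene Igf2bp2 16.2-fold, Olr1386 12.7-fold, Gfra3 12.4-fold, and Fa2h 11.4-fold, and Cyp4b1 was lower as well (-3.46 ± 0.36). Replication genes rose in 30 of 32 with none falling (30 over the list alone, camera adjusted p = 9.74e-15, adjusted p = 0.242 with an estimated correlation), and mitosis genes in 25 of 27 with none falling (25 over the list alone, camera adjusted p = 8.96e-13, adjusted p = 0.242 with an estimated correlation). Tk1 was 3.37-fold and Ccna2 2.72-fold higher. Cholesterol synthesis genes rose in 22 and fell in 1 of 23, the same over the list alone (camera adjusted p = 4.77e-08, adjusted p = 0.242 with an estimated correlation), with Fdps 2.79-fold and Cyp51 2.20-fold higher. Histone genes rose in 11 and fell in 1 of 14, also over the list alone (camera adjusted p = 0.000990, adjusted p = 0.428 with an estimated correlation).

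Endoplasmic reticulum stress and amino acid response genes fell in 25 and rose in 1 of 31 at 10 d, the same over the list alone (camera adjusted p = 3.11e-10, adjusted p = 0.242 with an estimated correlation), with Sel1l 4.31-fold, Hspa5 3.26-fold and Herpud1 2.82-fold lower. Hypoxia and glycolysis genes rose in 21 and fell in 1 of 32 (22 and 1 over the list alone, camera adjusted p = 3.90e-07, adjusted p = 0.242 with an estimated correlation), led by Pgk1 (1.99-fold) and Aldoc (4.59-fold). Oxidative phosphorylation genes rose in 26 and fell in 1 of 37, as they did over the list alone (camera adjusted p = 4.77e-08, adjusted p = 0.289 with an estimated correlation). Ribosomal protein genes rose in 18 and fell in 1 of 39, as over the list alone (camera adjusted p = 0.0272, adjusted p = 0.649 with an estimated correlation), by a median of 0.08 over the list, with Rpl11 well above it at 0.62 ± 0.07. These genes have many processed pseudogenes that share their reads. Axon guidance genes fell in 9 and rose in 3 of 19 (camera adjusted p = 0.0216, adjusted p = 0.376 with an estimated correlation), and p53 targets fell in 9 and rose in 2 of 16 (camera adjusted p = 0.0154, adjusted p = 0.376 with an estimated correlation), with the same counts for both over each list alone. Krt8 (0.86 ± 0.10) and Krt18 (1.24 ± 0.19) were again higher together with the division genes, while Cldn4 (-0.50 ± 0.07) and Epcam (-0.37 ± 0.09) of the same list were lower. These were 2 higher and 2 lower of 6 epithelial genes, as over the list alone (camera adjusted p = 0.925), with a median of -0.13 and a mean of 0.08, which differ in sign. The α1ACT 10 d libraries also had the highest share of reads outside annotated genes of the 8 groups, 52.5% ± 0.299 against 50.9% ± 0.364 in the vector libraries of that time (SD, n = 3). Of 9994 genes, 5886 differed by edgeR's quasi-likelihood test, 2950 higher and 2936 lower, and 684 by at least 2-fold.

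**Figure D4:**
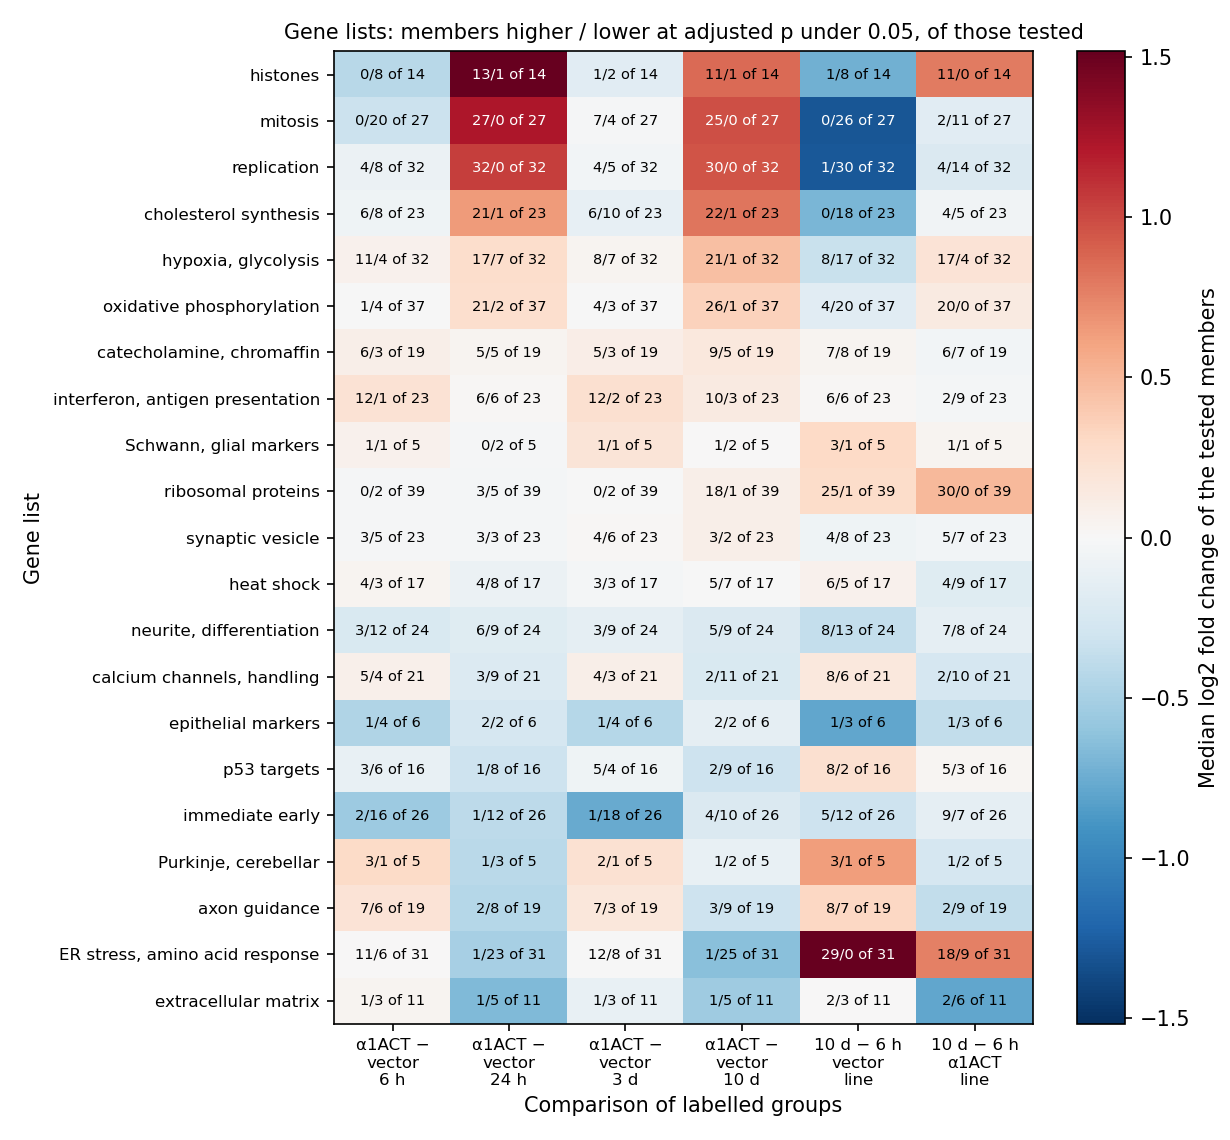
Median log2 fold change of the tested members of each gene list (rows) in the 4 line differences and in 10 d against 6 h within each labelled line (columns); each cell gives the members higher and lower at an edgeR adjusted p under 0.05, of those tested. Mitosis genes were 27 higher and 0 lower at 24 h, and 0 higher and 20 lower at 6 h.

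Averaged over the 4 labelled times, Kcnh1 was 3.38-fold higher (1.76 ± 0.10), Mgll 2.67-fold, Fam64a 2.66-fold, Hist1h1a 2.61-fold, Smtnl2 2.56-fold and the laminin Lamb3 2.55-fold. Fosl1 was 5.45-fold lower (-2.45 ± 0.25), Gfra3 5.02-fold, Cyp4b1 4.05-fold, Fam129a 3.31-fold, Shc4 3.03-fold and the cystine transporter Slc7a11 3.01-fold. Each of these 12 genes had the same sign at all 4 times, as the naming rule for the average required. Replication genes rose in 32 of 32 (camera adjusted p = 1.53e-13, adjusted p = 0.288 with an estimated correlation) and mitosis genes in 27 of 27 (camera adjusted p = 2.02e-11, adjusted p = 0.296 with an estimated correlation). Immediate early genes fell in 19 of 26 with none rising (camera adjusted p = 4.68e-05, adjusted p = 0.288 with an estimated correlation), with Atf3 2.89-fold, Klf6 1.99-fold and Jun 1.85-fold lower. Over the lists alone the counts were 32, 27 and 19. Among markers of other cell types, fibroblast genes were higher in 3 of 3, Schwann and glial genes higher in 1 and lower in 3 of 5 (camera adjusted p = 0.839), epithelial genes higher in 2 and lower in 2 of 6 (0.629), and immune genes lower in 1 of 3 with none higher. These counts were the same over each list alone. The mean share of reads outside annotated genes was higher in the α1ACT libraries at each of the 4 times, from 49.6% ± 0.587 against 48.7% ± 0.842 at 6 h to 52.5% ± 0.299 against 50.9% ± 0.364 at 10 d (SD, n = 3). By edgeR's quasi-likelihood test 6627 of 9994 genes differed on average, 3355 higher and 3272 lower, and 150 by at least 2-fold. The average hides opposite differences: of 1482 genes called at all 4 times, 349 were higher at each, 408 lower at each, and 725 changed sign between times. At 6 h and 24 h, 557 genes were higher and 625 lower at both, against 545 and 610 expected from unrelated calls. At 24 h and 3 d they were 542 and 578 against 530 and 560. At 6 h and 10 d they were 708 and 707 against 604 and 622. For 3 d and 10 d they were 658 and 648 against 588 and 571. Equal sign at all 4 times thus does not by itself show a lasting line difference.

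The line difference, by the labels, itself depended on the labelled time. Such a pattern would also follow if the file names are right, since these would then be differences between times. Unc5b was 1.93-fold higher at 6 h and 2.10-fold higher at 3 d, but 4.81-fold lower at 24 h and 4.74-fold lower at 10 d (interaction adjusted p = 4.63e-17, edgeR quasi-likelihood test). The chromatin reader Zmynd8 went the same way, 1.80-fold and 1.80-fold higher at 6 h and 3 d and 2.38-fold and 2.32-fold lower at 24 h and 10 d. Fdps was 1.40-fold and 1.53-fold lower at 6 h and 3 d and higher at the other times, as were the pyruvate dehydrogenase kinase Pdk3 (1.21-fold and 1.32-fold lower, 2.47-fold and 2.64-fold higher) and Tagln2 (1.59-fold and 1.40-fold lower, 1.88-fold and 1.90-fold higher). Sel1l differed by -0.04 ± 0.08 at 6 h and -0.01 ± 0.08 at 3 d, neither past the threshold, and fell at 24 h and 10 d. In all 5763 of 9994 genes passed this test. Across genes, the line differences at 6 h and 3 d had a Pearson correlation of 0.820, and 4 of the 3064 genes called at both went opposite ways. Those at 24 h and 10 d correlated at 0.884, with 10 of 4622 jointly called genes going opposite ways. The correlation was 0.0157 between 6 h and 24 h, where 1239 of 2421 jointly called genes went opposite ways, and no other pair of times exceeded 0.0680. Genes are not independent replicates, and these 6 correlations have no p-value.

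Within the vector line, 10 d against 6 h showed higher endoplasmic reticulum stress and amino acid response genes and lower mitosis genes, though neither list passed camera with an estimated correlation (adjusted p = 0.233 and 0.402 with an estimated correlation). Should the file names be right, this comparison and the joint test over the labelled times mix line with time. Of 31 genes of that response 29 rose and none fell, as over the list alone (camera adjusted p = 4.00e-16, adjusted p = 0.233 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, 34.0-fold higher (5.09 ± 0.15), Sesn2 7.06-fold, the stress transcription factor Ddit3 5.83-fold and Herpud1 4.45-fold. Mitosis genes fell in 26 of 27 (camera adjusted p = 4.00e-16, adjusted p = 0.402 with an estimated correlation), replication genes fell in 30 and rose in 1 of 32 (camera adjusted p = 1.35e-14, adjusted p = 0.402 with an estimated correlation), and cholesterol synthesis genes fell in 18 of 23 with none rising (camera adjusted p = 2.04e-06, adjusted p = 0.402 with an estimated correlation), each with the same counts over the list alone. Ccna2 was 4.61-fold lower, Mcm6 3.79-fold lower and Fdps 2.65-fold lower. Ribosomal protein genes rose in 25 and fell in 1 of 39 (camera adjusted p = 0.00129, adjusted p = 0.681 with an estimated correlation), oxidative phosphorylation genes fell in 20 and rose in 4 of 37 (camera adjusted p = 0.00332, adjusted p = 0.681 with an estimated correlation), p53 targets rose in 8 and fell in 2 of 16 (camera adjusted p = 0.0380, adjusted p = 0.681 with an estimated correlation) and hypoxia and glycolysis genes fell in 17 and rose in 8 of 32 (camera adjusted p = 0.0474, adjusted p = 0.681 with an estimated correlation), all unchanged in number over the lists alone. Immediate early genes were lower in 12 and higher in 5 of 26, as over the list alone (camera adjusted p = 0.161, median -0.31), and Myc of that list rose 13.1-fold. Krt8 fell 4.13-fold and Krt18 4.81-fold. Epithelial genes fell in 3 and rose in 1 of 6, 4 and 1 over the list alone (camera adjusted p = 0.0843). Schwann and glial genes rose in 3 and fell in 1 of 5, as over the list alone (camera adjusted p = 0.537). Of 3 fibroblast genes 2 fell and none rose (3 fell over the list alone), and of 3 immune genes 1 rose and none fell, also over the list alone. Reads outside annotated genes were 50.9% ± 0.364 at 10 d and 48.7% ± 0.842 at 6 h (SD, n = 3).

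Trim66 was 89.4-fold higher at 10 d than at 6 h in the vector line (6.48 ± 0.33), at 31.0 ± 4.42 against 0.334 ± 0.0966 CPM (SD, n = 3), and the kinesin Kif21b 69.3-fold. In some of these genes 1 group held no more than 3 counts per library on average, and summed counts are given. Inhbe, a subunit of activins, had 694 against 4 counts, a 152-fold difference (95% counting interval 59.0 to 559). Il9r had 258 against 2 counts, a 113-fold difference (95% counting interval 30.9 to 937). Stard8 had 245 against 2 counts, a 107-fold difference (95% counting interval 29.4 to 889.9). Olr1386 had 210 counts at 10 d and 0 at 6 h, at least 20.4-fold higher against a floor of 3 counts per library. The cytokine Il33 fell. It had 6 against 142 counts, a 27.1-fold difference (95% counting interval 12.1 to 75.0). Mpzl2 was 26.5-fold lower, Sprr1a 24.1-fold, Dclk1 22.4-fold, Fosl1 20.9-fold and the galectin Lgals3 18.4-fold. Btg1 (1.56 ± 0.11), Atp2b2 (0.50 ± 0.09) and Grn (0.46 ± 0.05) rose, and Cacna1a (0.22 ± 0.12) did not pass. By edgeR's quasi-likelihood test 7163 of 9994 genes changed over the 4 labelled times, and 6429 differed at 10 d from 6 h, 3308 higher and 3121 lower, 1074 of them by at least 2-fold.

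Within the α1ACT line the largest rises of 10 d over 6 h by the fixed rule were those of Inhbe, Slc7a11 (20.2-fold), the inflammatory caspase Casp4 (14.6-fold), Chac1 (13.7-fold), Trim66 (10.6-fold) and Rgs2 (10.3-fold). Here too the time comparisons mix line with time if the file names are right. Inhbe had 160 against 4 counts, a 50.1-fold difference (95% counting interval 19.2 to 186). Slc7a11 stood at 133 ± 46.5 against 6.56 ± 1.72 CPM (SD, n = 3). Lgals3 was 17.0-fold lower, Sprr1a 13.7-fold, the secretory granule protein gene Sytl4 4.58-fold, the potassium channel Kcnc4 4.52-fold and Rab7b 4.46-fold, and Plekhb1 was lower as well (-3.46 ± 0.40). Ribosomal protein genes rose in 30 of 39 with none falling, as over the list alone (camera adjusted p = 6.16e-12, adjusted p = 0.592 with an estimated correlation), by a median of 0.49, led by Rplp1 (0.85 ± 0.07) and Rplp0 (0.60 ± 0.06). The endoplasmic reticulum stress and amino acid response list split, with 18 higher and 9 lower of 31, also over the list alone (camera adjusted p = 6.73e-06, adjusted p = 0.592 with an estimated correlation). Its leading members Ddit3 (7.29-fold), Trib3 (4.31-fold) and the mitochondrial folate enzyme Mthfd2 (3.29-fold) rose. Histone genes rose in 11 of 14 with none falling (camera adjusted p = 0.000190, adjusted p = 0.592 with an estimated correlation), oxidative phosphorylation genes rose in 20 of 37 with none falling (camera adjusted p = 0.00255, adjusted p = 0.592 with an estimated correlation), and hypoxia and glycolysis genes rose in 17 and fell in 4 of 32 (camera adjusted p = 0.00114, adjusted p = 0.592 with an estimated correlation). Over the lists alone 11, 20 and 18 rose. With library sizes in place of scaling factors 14 oxidative phosphorylation genes rose and 2 fell.

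In the same line replication genes were lower in 14 and higher in 4 of 32 (camera adjusted p = 0.0187, adjusted p = 0.798 with an estimated correlation) and mitosis genes were lower in 11 and higher in 2 of 27 (camera adjusted p = 0.0430, adjusted p = 0.798 with an estimated correlation). Adjusted over the lists alone, 15 replication genes fell and 5 rose, and 11 mitosis genes fell and 2 rose. Whether either list changed differently in the 2 lines was not tested. Btg1 (0.46 ± 0.11) rose and Atp2b2 (-0.60 ± 0.09) fell. Epithelial genes were lower in 3 and higher in 1 of 6, 4 and 1 over the list alone (camera adjusted p = 0.0890, median -0.37), with none higher under RLE factors or library sizes. Schwann and glial genes were higher in 1 and lower in 1 of 5 (camera adjusted p = 0.818), fibroblast genes higher in 1 and lower in 2 of 3, and immune genes higher in 1 and lower in 1 of 3, each as over the list alone. Reads outside annotated genes were 52.5% ± 0.299 at 10 d and 49.6% ± 0.587 at 6 h (SD, n = 3). Grn (-0.15 ± 0.05, adjusted p = 0.0184) and Cacna1a (-0.30 ± 0.12, adjusted p = 0.0446) also fell. The call of Grn ended without replicate 3 of 10 d (0.0526) or of 6 h (0.0536). That of Cacna1a ended in DESeq2 (0.0575) and without each library of the 2 groups in turn except replicate 3 of 6 h, at adjusted p = 0.0611 to 0.190. By edgeR's quasi-likelihood test 5530 of 9994 genes changed over the 4 labelled times, and 4795 differed at 10 d from 6 h, 2404 higher and 2391 lower, 367 by at least 2-fold. The share of higher genes among those called was 50.1%, and 41.4% with library sizes in place of scaling factors. Without all libraries numbered 1 the count over the 4 times was 3407.

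The remaining lists did not pass as sets in the line differences named here, although single members did. Catecholamine and chromaffin cell genes at 10 d were higher in 9 and lower in 5 of 19 (camera adjusted p = 0.387), with the receptor tyrosine kinase Ret 2.57-fold and Th, the tyrosine hydroxylase of dopamine synthesis, 1.64-fold higher and the transcription factors Phox2a 1.86-fold and Gata2 1.83-fold lower. At 6 h, 24 h and 3 d that list had 6, 5 and 5 higher and 3, 5 and 3 lower (adjusted p = 0.235, 0.829 and 0.593), and at 24 h its median of 0.04 and mean of -0.02 differed in sign. Calcium channel and calcium handling genes at 10 d were lower in 11 and higher in 2 of 21 (adjusted p = 0.0918), with the N-type channel gene Cacna1b 2.14-fold lower and the inositol trisphosphate receptor Itpr1 1.62-fold higher. That list was lower in 9 and higher in 3 at 24 h (adjusted p = 0.166, median -0.21), but higher in 5 and lower in 4 at 6 h (0.709, median 0.08) and higher in 4 and lower in 3 at 3 d (0.915, median 0.08). Synaptic vesicle genes at 6 h were higher in 3 and lower in 5 of 23 (adjusted p = 0.709), and Rab3a was 2.50-fold and Rph3a 2.11-fold higher. The mean of that list was above 0 and its median, -0.01, below it, and at 24 h, 3 d and 10 d it had 3, 4 and 3 higher and 3, 6 and 2 lower (adjusted p = 0.885, 0.915 and 0.520). Purkinje and cerebellar genes were mostly too low to test, and 5 of 24 were tested. Of these 5, 3 were higher and 1 lower at 6 h (adjusted p = 0.709, median 0.29), 1 higher and 3 lower at 24 h (0.549, median -0.41), 2 higher and 1 lower at 3 d (0.915, median 0.23) and 1 higher and 2 lower at 10 d (0.863, median -0.11). With RLE factors 1 was higher and 1 lower at 3 d. Catecholamine genes at 3 d were 5 higher and 5 lower with RLE factors, and 5 and 2 with library sizes. Heat shock genes at 24 h were higher in 4 and lower in 8 of 17 (adjusted p = 0.537), and at 6 h, 3 d and 10 d that list had 4, 3 and 5 higher and 3, 3 and 7 lower (adjusted p = 0.709, 0.915 and 0.411). With library sizes heat shock genes were higher in 6 and lower in 2 at 6 h, and higher in 5 and lower in 2 at 3 d, where their median turned from below 0 to above it. Synaptic vesicle genes at 6 h were 3 higher and 7 lower with RLE factors, and 4 and 4 with library sizes, which put their median above 0. Over the lists alone the counts of higher and lower members were the same, except for catecholamine genes at 6 h (7 and 3) and 3 d (5 and 5), synaptic vesicle genes at 6 h (3 and 4) and 24 h (2 and 3) and heat shock genes at 6 h (5 and 3) and 3 d (3 and 2). Whether any of these lists differed between times was not tested.

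Markers of other cell types were few. Epithelial genes at 6 h were lower in 4 and higher in 1 of 6 (camera adjusted p = 0.128), and Schwann and glial genes at 24 h were lower in 2 of 5 with none higher (adjusted p = 0.674), the same over each list alone. Of the glial genes 1 was higher at each of 6 h, 3 d and 10 d, and 1, 1 and 2 were lower (adjusted p = 0.784, 0.915 and 0.748), with a mean below 0 at 10 d and a median above it, which fell below 0 with RLE factors or library sizes. Of 3 tested fibroblast genes Twist1 (0.90 ± 0.07), Fbln1 (0.32 ± 0.08) and Dcn (1.33 ± 0.43) rose at 10 d, and of 3 immune genes Cd68 (-1.39 ± 0.28) and Fcer1g (-1.08 ± 0.44) fell and Lyz2 (-0.25 ± 0.52) did not pass, again as over the lists alone. Fibroblast genes were higher in 1, 2 and 2 at 6 h, 24 h and 3 d with none lower, and no immune gene passed at those times. The 10 d call of Dcn ended without α1ACT replicate 1 (adjusted p = 0.0598), and that of Fcer1g in DESeq2 (0.101), with no filter on low counts (0.0782) and without α1ACT replicate 2 (0.271) or 3 (0.0521) or vector replicate 1 (0.119) or 2 (0.0631). Snhg11, the one tested nuclear-retained RNA, rose at 6 h (0.39 ± 0.09) and 3 d (0.24 ± 0.09, edgeR adjusted p = 0.0378) and fell at 24 h (-0.45 ± 0.08) and 10 d (-0.30 ± 0.09). The 3 d call ended without α1ACT replicate 1 (0.223) or 3 (0.0826) or vector replicate 2 (0.124) or 3 (0.174), and the 10 d call without vector replicate 2 (adjusted p = 0.0581).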

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

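The pairing of groups by the time in the file names and the correlation that bears on a lasting line difference were tests chosen after the distances between groups had been seen, while the test of the line in the file names and the counts over other splits of the samples were set down before their results.

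The line difference differed between the labelled times for 5763 of 9994 genes in edgeR's interaction test. The adjusted p was 4.63e-17 for Unc5b, 1.30e-16 for Zmynd8, 2.81e-15 for Fdps and 4.74e-15 for each of Pdk3, Sel1l and Tagln2. It was 8.75e-05 for Cacna1a, 3.40e-09 for Grn, 4.60e-09 for Atp2b2 and 5.50e-07 for Btg1. Of the 34 genes named for a line difference at one time, 30 passed this test, against 57.7% of all tested genes. These genes were picked from the same data for large differences at one time, which favours passing. Unc5b at 6 h stood at 138 ± 11.4 CPM in the vector line and 266 ± 20.1 CPM in the α1ACT line, and at 24 h at 761 ± 81.5 and 158 ± 28.6 CPM (SD, n = 3).

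The name of the deposited file gave another time point than the label for 18 of the 24 libraries, and within each labelled line the 6 h group lay close to the 3 d group and the 24 h group close to the 10 d group. A lasting difference between the lines with the labels right would give like line differences at 6 h and 24 h, but these correlated across genes at 0.0157, against 0.820 for 6 h and 3 d, which argues against it. If the file names and not the labels gave the true line and time, groups that share a time in the file names should lie closest, and of the 105 pairings of the 8 groups that pairing ranked 1, with a mean distance of 0.204 against 0.298 for the next and 0.452 for the pairing by labelled time, which is consistent with labels exchanged between groups as a hypothesis. The line in the file names alone explained 4.49% of the variance of log2 CPM (rank 28 of the 35 splits of the groups into 4 and 4) and the labelled line 19.6% (rank 5), while time explained 74.4% by the file names and 41.8% by the labels; the larger share of the labelled line had been set down as evidence against the file names, but that bound took line to be the larger difference, and by the file names the labelled lines part 6 h and 3 d from 24 h and 10 d, so on this value the line of the file names and that of the labels cannot be told apart. A line difference that turns with the labelled time, with the labels right, stays open and untested, since no feature in the counts marks the transgene.

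With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 4162 genes at 6 h, 5542 at 24 h, 3934 at 3 d, 5886 at 10 d and 4795 for 10 d against 6 h in the α1ACT line, where the highest other split called 0, and 6429 for 10 d against 6 h in the vector line, where the highest other called 1. At 3 d, where the replicate numbers pair the samples, the 3 other splits that part all 3 pairs called at most 0 genes and the remaining splits keep pairs together. With times reassigned within a line, only 1 of 100 splits, the real one, gave as many genes. The highest other count was 3009 against 7163 genes for the vector line and 263 against 5530 for the α1ACT line. Other splits mix libraries of different groups, so the real one leads whenever the libraries of a group are alike. The counts make a random assignment of single libraries unlikely. They cannot exclude a difference of culture or batch that the libraries of a group share. With lines reassigned within each time, 1 of 100 splits, the real one, gave as many genes for the average line difference, with 1806 as the highest other against 6627. For the interaction 2 of 100 did, the real one included, so few random assignments reach such a count, though not only the real one. The other such split called 6335 genes against 5763, and at 3 of the 4 times it parted the libraries as the labels do or in exact mirror image. The next highest called 5093. The same limit on shared differences of culture or batch holds for these counts, as it does for a difference between the 2 stable lines that is not due to α1ACT.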

How the results depend on the processing

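Leaving out all libraries of 1 replicate number and using library sizes alone were alternatives chosen after the data were seen, as was the contrast of 3 d and 10 d against 6 h and 24 h, and the other alternatives were planned. With DESeq2 the counts of genes were 4050, 5377, 3783 and 5713 for the line differences at 6 h, 24 h, 3 d and 10 d, 6502 for the average, 6995 and 5400 for time in the vector and α1ACT lines, 6260 and 4588 for 10 d against 6 h in them, 5655 for the interaction and 1534 for the added contrast, each within 1.5 times the main count, as were those with RLE factors, with no filter and with only the groups compared. Leaving out 1 library or 1 replicate number gave 2580 to 3984 genes at 6 h, 4437 to 5352 at 24 h, 2449 to 3640 at 3 d, 4762 to 5701 at 10 d and 5671 to 6608 on average. It gave 5952 to 7103 and 3407 to 5601 over time in the vector and α1ACT lines, 5413 to 6179 and 3272 to 4625 for 10 d against 6 h, 4402 to 5844 for the interaction and 314 to 2062 for the added contrast. No single library moved a count over 1.5 times. Leaving out a whole number leaves 2 libraries per group and 8 fewer in the fit, and without numbers 1 and 3 the counts were 2580 and 2637 at 6 h, 2462 and 2449 at 3 d, 314 and 504 for the added contrast, and 3407 without number 1 for time in the α1ACT line. Without number 2 they were 3984, 3640, 2062 and 5601. The libraries numbered 2 stood apart: in all 8 groups numbers 1 and 3 were the closest pair, at a chi-square per degree of freedom of 1.98 to 5.28, against 3.65 to 11.3 for pairs with number 2. Deviations from the group means correlated at a mean of 0.171 among libraries numbered 2, 0.0682 among those numbered 1 and 0.0538 among those numbered 3. Whether this caused the changes in the counts was not tested. Of the 21 lists tested, camera with its preset correlation called 4, 11, 2 and 10 at 6 h, 24 h, 3 d and 10 d, 11 on average, 8 and 7 for 10 d against 6 h in the vector and α1ACT lines, and 10 for the added contrast. With an estimated correlation it called 0 in the first 7 of these and 1 in the last. Both settings allow for correlation between members, and why their calls differ was not tested. The fry test, which asks another question, called 7, 16, 7, 18, 16, 15, 13 and 7 in the same order. Of 134 results for named genes, DESeq2 ended 1, RLE factors ended none, no filter added 1, a fit of only the groups compared ended 1 and added 1 of 96, and leaving out a library ended 6. Of 707 for list members these settings ended 9, 3, 4, 2 (of 512) and 47. None was reversed. Library sizes alone raised the share of higher genes from 49.1% to 60.3% at 6 h, and moved it from 50.6% to 59.7% at 3 d and from 50.1% to 41.4% for 10 d against 6 h in the α1ACT line, with no median shift over 0.1. The shallowest group, α1ACT 10 d, has the highest floors, up to 0.346 CPM, and differences of genes near that level are not detectable at this depth.

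The replicate number as a block gave 4389, 5734, 4147 and 6097 genes at 6 h, 24 h, 3 d and 10 d, 6791 on average, 7349 and 5775 for time in the vector and α1ACT lines, 6585 and 4982 for 10 d against 6 h, 5977 for the interaction and 1786 for the added contrast. At 3 d, where the numbers pair the samples, the block brought Hist1h1a past the threshold (adjusted p = 0.0172) and changed no other call of a gene or list named there. Of the 24 libraries 18 correlated best with their own number. Mean correlations were 0.0975 for same-numbered libraries over all pairs of groups and -0.0478 for different numbers. A tie between same-numbered libraries was thus not confined to 3 d. In the comparisons other than 3 d the rule for pairing was not met. The lowest correlation of a same-numbered pair was 0.0980 at 6 h, beside 0.164 and 0.342, and lower in the rest. There the block passed 4, 10, 10, 11, 7, 6 and 11 lists at 6 h, 24 h, 10 d, on average, for 10 d against 6 h in the vector and α1ACT lines and for the added contrast, without extracellular matrix genes at 24 h (0.0583), hypoxia genes in the vector line (0.0539) and mitosis genes in the α1ACT line (0.0506), and with calcium genes gained in the added contrast (0.0343, and just above the threshold without the block). It brought Atp2b2 at 24 h past the threshold (0.0474).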

Other observations

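The contrast described here and the pairing by file names were tests chosen after the distances between groups had been seen, the contrast being 3 d and 10 d against 6 h and 24 h averaged over both labelled lines. It compares the 2 labelled groups within each close pair, and it is also the contrast of the 2 lines by the file names, where the labelled 3 d and 10 d libraries bear the name of the α1ACT line and the 6 h and 24 h libraries that of the vector line.

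In this contrast the hyperpolarisation-activated channel gene Hcn4 was 3.02-fold higher at the labelled 3 d and 10 d (1.60 ± 0.09), the prostaglandin E receptor Ptger3 2.83-fold, Prkcdbp 2.45-fold, Olfm2 2.43-fold, Fa2h 2.27-fold and Penk, the proenkephalin gene, 2.26-fold. The collagenase Mmp13 was 4.78-fold lower (-2.26 ± 0.23), with wide spread in some groups, such as 133 ± 65.0 CPM in the vector line at 6 h and 35.2 ± 2.63 CPM at 3 d (SD, n = 3). Diras2 was 2.02-fold lower, the guidance cue Ntn1 1.99-fold, Prex2 1.98-fold, Rab7b 1.81-fold and Plek2 1.80-fold. Hcn4 stood at 1.05 ± 0.316 and 5.20 ± 0.452 CPM in the vector line at 6 h and 24 h, and at 3.88 ± 0.425 and 16.9 ± 0.844 CPM at 3 d and 10 d. Neurite and neuronal differentiation genes rose in 11 and fell in 2 of 24 (11 and 3 adjusted over the list alone, camera adjusted p = 1.46e-05, adjusted p = 0.0156 with an estimated correlation), among them Stmn2 (0.28 ± 0.03), L1cam (0.36 ± 0.04), the neurofilament Nefl (0.35 ± 0.04) and peripherin, Prph (0.18 ± 0.03). Synaptic vesicle genes rose in 4 of 23 with none falling, also over the list alone (camera adjusted p = 0.0118, adjusted p = 0.571 with an estimated correlation), led by Syn2 (0.65 ± 0.04). The myelin gene Pmp22, on the Schwann and glial list, rose by 0.79 ± 0.06 on the log2 scale, and the myelin gene Mbp of that list fell (-0.11 ± 0.03), with 1 higher and 1 lower of 5, as over the list alone (camera adjusted p = 0.408, median 0.04). Epithelial genes had 1 higher and 1 lower of 6 (1 and 2 over the list alone, camera adjusted p = 0.351), fibroblast genes 1 higher and 1 lower of 3, and no immune gene passed, the last counts also over the lists alone. The mean share of reads outside annotated genes was higher at the later time of each close pair, by little next to its spread at 6 h and 3 d. In the vector line it was 48.7% ± 0.842 at 6 h and 48.8% ± 0.571 at 3 d, and 50.4% ± 0.362 at 24 h and 50.9% ± 0.364 at 10 d. In the α1ACT line it was 49.6% ± 0.587 and 49.9% ± 0.286, and 51.6% ± 0.589 and 52.5% ± 0.299 (SD, n = 3).

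Mitosis genes fell in 10 of 27 and replication genes in 11 of 32 with none rising in either (14 and 13 over the lists alone), each with camera adjusted p = 3.22e-06 and adjusted p = 0.571 with an estimated correlation. The list medians were -0.11 and -0.11, with -0.20 ± 0.05 for Ccnb2 and -0.16 ± 0.04 for Rfc3. Of 16 p53 targets 8 rose and none fell, 9 rising over the list alone (camera adjusted p = 0.000192, adjusted p = 0.461 with an estimated correlation), with Cdkn1a, the inhibitor of cyclin-dependent kinases, at 0.29 ± 0.06. Heat shock genes rose in 5 of 17 (5 higher and 1 lower over the list alone, camera adjusted p = 0.0118, adjusted p = 0.571 with an estimated correlation). Of the 4 genes tied to α1ACT, Btg1 (0.19 ± 0.05, adjusted p = 0.0164) and Atp2b2 (0.14 ± 0.04, adjusted p = 0.0387) were higher, while Grn (-0.03 ± 0.03, adjusted p = 0.532) and Cacna1a (0.03 ± 0.06, adjusted p = 0.805) did not pass. Over the list alone 2 were higher and 0 lower. The call of Atp2b2 ended with library sizes in place of scaling factors (0.0565). It also ended on leaving out, in turn, vector replicate 2 or 3 of 6 h or 24 h, 1 or 3 of 3 d or 2 of 10 d, or α1ACT replicate 1 or 2 of 6 h, 1 or 3 of 24 h or 10 d or 1 of 3 d, with adjusted p from 0.0507 upward. By edgeR's quasi-likelihood test 1562 of 9994 genes passed, 825 higher and 737 lower, and 29 by at least 2-fold. The share of higher genes was 52.8%, and 47.9% with library sizes in place of scaling factors. Without the libraries numbered 1 the count was 314 and without those numbered 3 it was 504.

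The contrast of the labelled 3 d and 10 d with 6 h and 24 h may hold the difference between the 2 stable lines, as a hypothesis that follows if the file names are right. With libraries reassigned within each close pair of groups, only 1 of 100 splits, the real one, called as many genes, and the highest other called 7 against 1562. Other splits mix libraries of different groups, so the real one leads whenever the libraries of a group are alike. A random assignment of single libraries is thus unlikely to give this count, which does not tell the file names from the labels. A difference of culture or batch that the libraries of a group share cannot be excluded by it. The pairing of the 8 groups by the time in the file names ranked 1 of 105. Within the single close pairs, 3 d against 6 h called 147 genes in the vector line and 106 in the α1ACT line, and 10 d against 24 h called 744 and 462. Of these 4 differences, any 2 correlated across genes at 0.330 to 0.428, and none share libraries. A change over the labelled times common to both lines, with the labels right, stays open.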
